A study of Mus musculus with 6 samples.

How the data were processed

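The data were 6 arrays of TRAP RNA from mouse cortex, 3 from mice given fluoxetine and 3 from mice given vehicle. Per the labels, ribosomes were affinity-purified, and 15 ng of RNA per sample went through 2 rounds of amplification before hybridisation to single-colour Affymetrix arrays. The mice had been backcrossed from FVB to C57BL/6 for 3 to 5 generations. The deposited values are intensity on a linear scale, 1 column per array, normalized with GCRMA per the submitters' processing notes; its version is not given in the sources used here. GCRMA subtracts a background modelled on probe sequence, makes the arrays' distributions alike and summarises the probes of a probe set. It therefore squeezes low intensities towards a floor, can hide a shift shared by most genes, and leaves no read depth. Scanner files were not analysed here. The scale was inferred from the values, which ran from 1.74 to 99076.

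The table held 45101 probe sets, of which 64 array controls were left out. Gene names came from a platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and no gene was named from the last 2 kinds. Symbols were looked up through gene identifiers in a RefSeq table (assembly GRCm38.p6, used for names and neighbouring genes only): 0 needed updating, and 204 were not in that table and kept the annotation's name. No genome build is given for the array values, so no coordinates are printed. Every sample column was used.

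Values were taken to log2 with no offset and no further scaling. Probe sets were tested where their geometric mean over the 6 arrays was at least 50, a form of the submitters' advice that does not look at the groups. This kept 22326 probe sets (49.6%), 20288 of them with 1 symbol, for 12248 genes, and left out 22711. The comparison was fluoxetine minus vehicle in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The median standard error was 0.154 in log2.

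Before the data were examined, 39 gene lists were fixed (pathways, complexes and markers of the labelled and other cell types), of which 37 had at least 5 measured members. Each gene was represented by its brightest probe set. Lists were tested with limma's camera at a preset correlation of 0.01, which compares the mean test statistic of a list with that of the other genes, with adjustment over lists. The same test with the correlation estimated per list, and fry, which tests whether a list moves one way on balance without comparing it with others, served as checks. A list with a median below 0 can therefore be tested as higher: this held for the meningeal, axon guidance, p11, neuropeptide receptor, ionotropic glutamate receptor, synaptic vesicle, proteasome, heat shock, layer 5, layer 6, endothelial and striatal lists. Bootstrap intervals of list medians came from 10000 draws of genes and do not cover the spread between arrays. Array means of each list were compared by an exact permutation test.

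The genes named in the text followed a rule fixed in the same way: S100a10 and the measured serotonin genes; 12 genes per direction, by size among those past the threshold with non-overlapping groups, otherwise by smallest unadjusted p among the non-overlapping; and up to 4 members per list, passed first and then by smallest p. Predicted genes and clone names were passed over. Because nothing passed, all of the second kind are of the fill-in type. Genes outside the rule were chosen after their values were seen: Fos, Nr4a1, Jun, the bright astrocyte markers Glul, Gjb6 and Slc1a2, the sex-linked genes, the serotonin genes below the filter and Jdp2.

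The tests were run first on 20 simulated data sets of 3 against 3 arrays and 22326 probe sets with 200 changed. They recovered 2.46%, 68.7% and 98.0% of changes of 0.5, 1 and 2 in log2, with 4.91% of calls false. A list shifted by 0.3 was called in 100% of them, and on average 0 lists were called where nothing changed; the simulated genes were independent, which real genes are not.

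Alternatives fixed beforehand were no filter, 2 group-wise readings of the level of 50, a minimum of 100, an offset of 16, quantile normalization, a shift to a common median, the replicate number as a block, trend and robust variance estimates, array weights, leaving out probe sets that can match several genes, averaging a gene's probe sets, a threshold of 0.10, and leaving out each array in turn.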

Results

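The series measured ribosome-bound messenger RNA from S100a10-expressing cells of the mouse cerebral cortex. In a bacTRAP line a tagged ribosomal protein is made in cells that use a chosen gene's control region, here that of S100a10. The tag allows the ribosomes of those cells to be pulled out of the tissue with the RNA they are translating (translating ribosome affinity purification, TRAP). S100a10 encodes p11, a small protein known to bind some serotonin receptors. Mice drank either fluoxetine, a serotonin reuptake inhibitor antidepressant, at 0.167 mg/ml with 1% saccharine, or the saccharine vehicle, over 15 to 18 days. The data comprised 3 fluoxetine and 3 vehicle arrays, each from a TRAP sample that the labels call a biological replicate. Whether a sample came from 1 animal or from several is not given in the sources used here, so p-values of single probe sets measure the spread between these samples. Camera p-values at the preset correlation take the genes of a list to vary almost independently. They therefore do not measure that spread for a list. The number of arrays limits the precision of every value below. The median intensity of the arrays lay between 47.3 and 48.6, the upper quartile between 498 and 574, and pairs of arrays correlated at 0.980 to 0.992 across probe sets. The submitters state that this line also labels some non-neuronal cells and advise using a published selection of probe sets, which was not used here.

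The comparison asks how prolonged fluoxetine changes the translated RNA of S100a10 cells. Immediate early genes, which neurons switch on soon after they are active, had the lowest median change of the 37 gene lists tested. Of 28 measured members, 27 were lower with fluoxetine and 1, Jun, was higher by 0.37 on the log2 scale, but by 0.043 without fluoxetine 1. The list median was −0.35 in log2, a fold of 0.786, with a 95% bootstrap interval over genes of −0.46 to −0.30. As a list they fell in limma's camera test with a preset correlation (adjusted p = 2.59e-07), but not with an estimated correlation (adjusted p = 0.927) or by fry (adjusted p = 0.839).

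The members with the smallest unadjusted p were Egr4, Homer1, Nr4a2 and Ier2. Egr4, a zinc finger transcription factor, measured 7.60 ± 0.26 with fluoxetine and 8.14 ± 0.11 with vehicle (log2 intensity, SD, n = 3 each). Homer1, a scaffold of the postsynaptic density, differed by −0.52 ± 0.16 (log2, SE), and its 4 other probe sets were lower too. Nr4a2, an orphan nuclear receptor, differed by −0.33 ± 0.12 and Ier2 by −0.81 ± 0.31, or −0.45 without vehicle 2. Fos (−0.42 ± 0.16) and Nr4a1 (−0.71 ± 0.28), named here after their values were seen, went the same way, at −0.27 and −0.46 without fluoxetine 1. None of the 28 passed limma's test over all probe sets or adjusted over the list alone, where the smallest adjusted p was 0.144, and 9 had an unadjusted p under 0.05, all lower.

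Averaged over the list, the fluoxetine arrays measured 10.26, 10.62 and 10.55 and the vehicle arrays 10.70, 11.12 and 10.77 in log2. The groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow (0.951 after Benjamini-Hochberg over the 37 lists). Fluoxetine 1 and vehicle 2 lay furthest out, with median deviations of −0.53 and 0.41 from the mean of the other arrays. Nuclear and non-coding transcripts, a list for RNA quality, moved on the same 2 arrays, by −0.33 (1 of 8 members above the others) and 0.36 (8 of 8). Without fluoxetine 1, 25 of the 28 members were lower, and without vehicle 2, 24 were. Without both arrays, 20 were lower, the list median was −0.22, and the camera call was lost (adjusted p = 0.221).

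**Figure D1:**
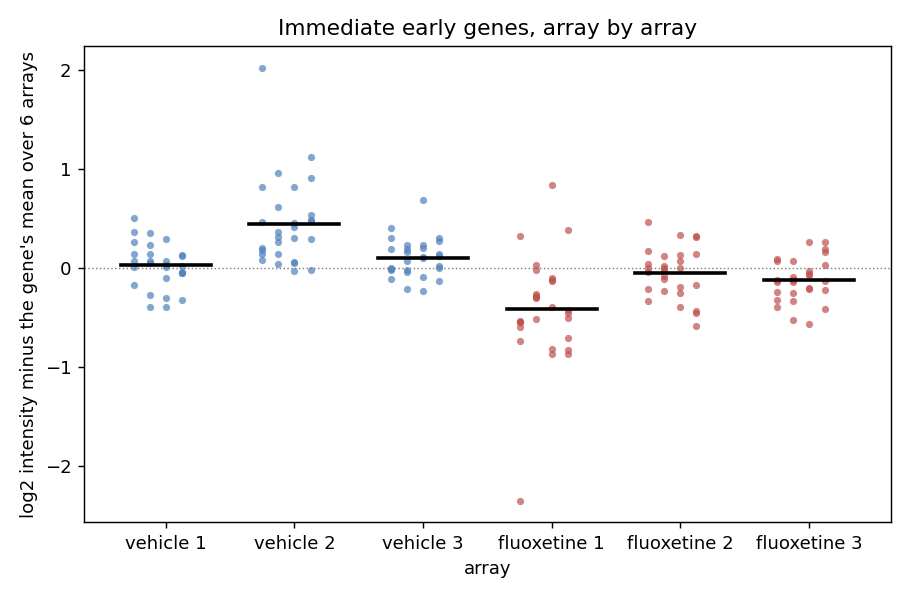
Each point is 1 of the 28 immediate early genes on 1 array, drawn as its log2 intensity minus that gene's mean over the 6 arrays, with vehicle in blue, fluoxetine in red and a black bar for the mean of the genes on that array. The 3 fluoxetine means lie below the 3 vehicle means, with fluoxetine 1 lowest and vehicle 2 highest.

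Probe set by probe set, none of the 22326 tested passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 563 probe sets, 165 higher and 398 lower with fluoxetine, where chance alone would give about 1116. That direction depended on the scaling: 267 were higher and 209 lower after quantile normalization, and 327 were higher and 170 lower when each array was shifted to a common median. The groups did not overlap for 1798 probe sets (8.05%), against 10% by chance with 3 arrays a side. In simulated arrays with the moderated spread of these, limma recovered 68.7% of changes of 1 on the log2 scale but 2.46% of changes of 0.5. Simulated genes varied independently, with no differences shared by an array, so these shares may not hold for the real arrays. There, 35 probe sets changed by at least 1 either way and none passed.

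The genes closest to a change, chosen by non-overlapping groups and smallest unadjusted p, therefore did not pass. Higher with fluoxetine were Sox9, a transcription factor of glia (8.77 ± 0.11 against 8.19 ± 0.04 in log2, SD, n = 3 each), and Rps6ka6, a ribosomal S6 kinase (difference 1.08 ± 0.25, SE). Pdyn, the precursor of dynorphin opioid peptides, differed by 0.53 ± 0.15, and Itga1, a collagen-binding integrin subunit, by 0.73 ± 0.19. The others were Mdc1, Tent5a, Myl4, Insrr, H2-T18, Gbp8, Nabp1 and Dyrk2, at 0.40 to 0.77. A second probe set of Myl4 went the other way (−0.34), and 1 of 2 further probe sets of Nabp1 and of Dyrk2 also did. Itga1, Pdyn, Mdc1, Myl4, Insrr, H2-T18, Gbp8 and Nabp1 were dim, with vehicle means of 5.80 to 6.11 in log2, just above the filter. Among probe sets below the filter, 72.6% were higher with fluoxetine, so a drift of low values cannot be told apart from changes of these genes.

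Lower with fluoxetine were Rab27a, a GTPase of vesicle secretion (8.04 ± 0.13 against 8.86 ± 0.30 in log2, SD, n = 3 each), and Cdk7, a kinase of transcription and the cell cycle (difference −0.44 ± 0.10, SE). S1pr5, a sphingosine-1-phosphate receptor, differed by −0.56 ± 0.13 and the F-box protein gene Fbxl12 by −0.64 ± 0.11. The others were Ptpn21, Gas2l3, Macrod1, Ehbp1l1, Cspp1, Dennd3, Tspan33 and Vps52, at −0.73 to −0.50. A second probe set of Vps52 was higher by 0.11, and 1 of 3 further probe sets of Cdk7 by the same amount. Gas2l3 and Ptpn21 were dim too, with fluoxetine means of 5.28 and 5.93 in log2.

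S100a10 itself measured 15.08 ± 0.09 with fluoxetine and 15.15 ± 0.07 with vehicle (log2, SD, n = 3 each), a difference of −0.07 ± 0.11 (SE). Without fluoxetine 3 the difference was −0.022, and the other probe set of S100a10 differed by −0.20. The serotonin list had 10 measured genes, 3 higher and 7 lower, and was not called as a list (median −0.05, limma camera adjusted p = 0.926). Its median was 0.00 after quantile normalization and 0.01 after the median shift. The largest differences were those of the receptors Htr3a (−0.20 ± 0.11), Htr2c (−0.16 ± 0.19) and Htr1a (−0.15 ± 0.12). Htr7 (−0.07), Htr1b (−0.03), Htr5a (0.00) and Htr1f (0.08) lay within their standard errors of 0. So did the monoamine oxidases Maoa (0.04) and Maob (−0.02) and Ddc, the enzyme of the last step of serotonin synthesis (−0.08). The filter on low values left out 9 further members, among them the serotonin transporter gene Slc6a4 and Tph1 and Tph2, and Htr2a had no probe set annotated to it alone. Htr4, a p11-binding receptor below the filter, read 7.09 on fluoxetine 1 and 4.69 to 5.45 on the other 5 arrays.

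Genes of the circadian clock also fell as a list at the preset correlation, with 18 of 20 measured members lower and a median of −0.15 (limma camera adjusted p = 0.039, and 0.927 with an estimated correlation). Per1, which is also an immediate early gene, differed by −0.49 ± 0.20 (SE), Ciart by −0.25 ± 0.12, Cry1 by −0.29 ± 0.16 and Cry2 by −0.18 ± 0.11, and none passed. The array means of the list did not overlap between groups (exact permutation p = 0.1, the smallest possible, and 0.951 after Benjamini-Hochberg). Of the 37 lists tested, 2 had array means that did not overlap, where 3 arrays against 3 give 10% by chance. Without Per1 the median was −0.14 and the call was lost (adjusted p = 0.074). The call was also lost without either of fluoxetine 1 and 2 or vehicle 1 and 2, at adjusted p of 0.157, 0.078, 0.296 and 0.059. It was also lost after quantile normalization (median −0.086, 15 of 20 lower, adjusted p = 0.086), with a minimum of 100 (adjusted p = 0.054), with a replicate block (adjusted p = 0.060) and without probe sets that can match several genes (adjusted p = 0.076), and after the median shift the median was −0.091.

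Astrocyte markers rose as a list at the preset correlation (limma camera adjusted p = 0.0014, and 0.927 with an estimated correlation), with 11 of 18 measured members higher, a median of 0.10 and a mean of 0.33. After quantile normalization and the median shift 16 of 18 were higher (medians 0.18 and 0.16), and without the filter the call was lost (adjusted p = 0.149). Sox9 passed limma's test adjusted over the list alone (adjusted p = 0.020), though its 2 other probe sets were higher by only 0.09 and 0.13. Gfap, the astrocyte intermediate filament, measured 12.13, 4.49 and 9.02 on the fluoxetine arrays and 4.70, 5.24 and 5.67 on the vehicle arrays. The water channel gene Aqp4 read 9.69, 7.44 and 9.11 against 8.02, 8.20 and 8.04. Some brighter members differed little: Gja1 by −0.15 ± 0.12, and Glul (−0.02), Gjb6 (−0.03) and Slc1a2 (−0.01) by less. Aldoc was higher by 0.21, but differed by −0.11 without fluoxetine 1. Averaged over the list, the fluoxetine arrays measured 11.02, 9.97 and 10.63 and the vehicle arrays 10.13, 10.22 and 10.29 (exact permutation p = 0.4). Of the 18 members, 14 lay above the other arrays on fluoxetine 1, 12 on fluoxetine 3 and 5 on fluoxetine 2. Without fluoxetine 1 the median was 0.01 and the call was lost (adjusted p = 0.071).

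Markers of pericytes and smooth muscle, cells of the vessel wall, fell as a list at the preset correlation, all 7 measured members being lower (median −0.25, limma camera adjusted p = 0.039, and 0.927 with an estimated correlation). Vtn differed by −0.41 ± 0.15 (SE), Acta2 by −0.59 ± 0.32, Tagln by −0.58 ± 0.33 and Rgs5 by −0.22 ± 0.14. The array means of the pericyte list overlapped between groups (exact permutation p = 0.2). The call was lost without fluoxetine 1, fluoxetine 3 or vehicle 3 (adjusted p of 0.313, 0.112 and 0.518), with medians of −0.19, −0.21 and −0.13. It was also lost without the filter, where 10 of 13 members were lower (median −0.097, adjusted p = 0.286), with array weights (adjusted p = 0.080), without probe sets that can match several genes (adjusted p = 0.088) and with a gene's probe sets averaged (median −0.16, adjusted p = 0.077). Interferon and inflammatory genes were called higher (adjusted p = 0.039, and 0.927 with an estimated correlation) with only 14 of 25 measured members higher and a median of 0.07. Irf9, a subunit of the interferon-activated transcription factor, differed by 0.56 ± 0.21 and Tnf by 0.26 ± 0.12, while Tap1 (−0.30 ± 0.15) and Irf1 (−0.19 ± 0.12) went the other way. The fluoxetine array means of the interferon list (8.93 to 9.01 in log2) lay inside the vehicle range (8.78 to 9.07, exact permutation p = 0.8). Without vehicle 1 the median was −0.02 (adjusted p = 0.431), and without fluoxetine 2 it was 0.02 (adjusted p = 0.276). The call was also lost without the filter (adjusted p = 0.286), with a minimum of 100 (median 0.0065, adjusted p = 0.062), after quantile normalization (adjusted p = 0.095) and after the median shift (adjusted p = 0.057).

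Cholesterol synthesis genes came close without passing, 18 of 20 measured members being lower (median −0.14, limma camera adjusted p = 0.051). Of the 18 other settings at the preset correlation, 9 called them. Their median was −0.074 after quantile normalization and −0.076 after the median shift. The fluoxetine arrays differed among themselves: 16 of the 20 members lay above the other arrays on fluoxetine 1 and 0 on fluoxetine 2, without which the median was −0.03 (adjusted p = 0.819). Tm7sf2, a sterol reductase gene, differed by −0.49 ± 0.12 (SE), and Insig1, whose protein restrains sterol synthesis, by −0.39 ± 0.13. The enzyme gene Idi1 differed by −0.32 ± 0.16 and Srebf2, the main transcription factor of the pathway, by −0.31 ± 0.19. Oligodendrocyte precursor markers (4 of 6 higher, median 0.17) and meningeal and choroid plexus markers (8 of 16 higher, median 0.00) each had an adjusted p of 0.091. In the first, Sox6 differed by 0.71 ± 0.24 and Pdgfra by 0.29 ± 0.16. In the second, the collagen genes Col1a1 (0.75 ± 0.24) and Col3a1 (0.58 ± 0.24) and the matrix gene Lum (0.48 ± 0.22) stood against Igf2 (−0.45 ± 0.16).

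Synaptic and signalling genes were not called as lists, all with limma camera adjusted p of 0.169 or more. Metabotropic glutamate receptors were lower in 5 of 6 cases (median −0.22; Grm2 −0.44 ± 0.17, SE), postsynaptic scaffolds in 22 of 26 (−0.13; Dlgap2 −0.90 ± 0.38) and potassium channels in 23 of 29 (−0.11; Kcnj9 −0.60 ± 0.15). Sodium and calcium channels had 18 of 24 members lower (median −0.15; Scn4b −0.42 ± 0.16), GABA receptors 8 of 10 (−0.07; Gabrd −0.43 ± 0.14) and cyclic AMP signalling 23 of 31 (−0.06; Adcy8 −0.47 ± 0.15). These counts depend on the scaling: after quantile normalization and the median shift, 5 and 6 of the 10 GABA receptors and 17 and 16 of the 31 cyclic AMP genes were lower. Under both, 14 of the 24 sodium and calcium channels and 19 of the 29 potassium channels were lower. Postsynaptic scaffolds had a median of −0.056 after quantile normalization and −0.072 after the median shift. Catecholamine, acetylcholine and histamine receptors had a median of −0.09 (Chrna4 −0.22 ± 0.12) and neurotrophins and growth factors one of −0.10, with Bdnf at 0.50 ± 0.32 (its other probe set 0.02). For p11 and its partners (median −0.03; Ppp1r1b 0.51 ± 0.30), neuropeptide receptors (−0.02; Crhr1 −0.56 ± 0.18) and ionotropic glutamate receptors (−0.03; Grik4 0.33 ± 0.19), scaling turned the sign of the median. So it did for synaptic vesicle genes (−0.05; Rims2 −0.35 ± 0.18) and axon guidance genes (−0.01; Plxna4 0.42 ± 0.13).

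Housekeeping lists were not called either, with limma camera adjusted p of 0.199 or more. Cytosolic ribosomal proteins had 28 of 29 measured members lower but by a median of only −0.09 (Rps19 −0.16 ± 0.13, SE), with 20 and 19 of the 29 lower after quantile normalization and the median shift (medians −0.041 and −0.028), and all tested genes together had a median of −0.06. The ribosomal list was called lower without the filter (adjusted p = 0.026) and without vehicle 1 (adjusted p = 0.0067). Oxidative phosphorylation (median −0.05), the proteasome (−0.04), the unfolded protein and heat shock response (−0.04) and the glucocorticoid response (−0.05) changed sign under 1 or both scalings. Glycolysis had a median of 0.03 and nuclear and non-coding transcripts one of −0.20, with Miat at −0.31 ± 0.11.

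Markers of the cortical neurons themselves were not called as lists, with limma camera adjusted p of 0.199 or more for each neuronal list. The medians were −0.04 for layer 5 (Crym −0.30 ± 0.14, SE), −0.05 for upper layers (Cyp39a1 −0.69 ± 0.28) and −0.01 for layer 6 (Moxd1 −0.43 ± 0.13), all of which changed sign with scaling. Interneuron markers had a median of −0.09, with Vip at 9.70 ± 0.06 against 10.09 ± 0.02 (log2, SD, n = 3 each). Striatal neuron markers had one of −0.08, with Penk at 0.85 ± 0.45 (SE) but 0.29 without fluoxetine 1. After quantile normalization and the median shift these medians were −0.012 and −0.034 for interneurons and −0.026 and −0.017 for striatal neurons. Of the other non-neuronal cells, oligodendrocyte markers had a median of −0.13 (Mal −0.33 ± 0.18), microglia and macrophages 0.06 (Cd68 0.95 ± 0.48) and endothelial cells −0.09 (Cldn5 −0.23 ± 0.16), at camera adjusted p of 0.791, 0.222 and 0.791. Under quantile normalization and the median shift, the medians were −0.071 and −0.069 for oligodendrocytes, 0.066 and 0.12 for microglia and −0.013 and −0.029 for endothelial cells. No red blood cell gene passed the filter, and 3 sex-linked genes did, too few to test (Uty −0.26 ± 0.34, Eif2s3y −0.09 ± 0.18 and Kdm5d −0.02 ± 0.19).

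Of 173 genes chosen by the naming rule, 100 had a change more than 1.5 times smaller, or reversed, without 1 array, most often fluoxetine 1 (39 genes). The count takes the weakest value over the 6 arrays left out in turn, and includes genes with changes near 0. The share over all probe sets is not given here, so the count does not set the named genes apart. No gene chosen for non-overlapping groups was among the 100, which that choice favours. Without fluoxetine 1, Ppp1r1b differed by 0.16, Aqp4 by 0.19, Cd68 by 0.51, Lum by 0.23, Col1a1 by 0.48, Pdgfra by 0.16 and Grik4 by 0.18. Likewise Tagln differed by −0.18, Cyp39a1 by −0.40, Crhr1 by −0.37, Grm2 by −0.26, Crym by −0.20 and Cldn5 by −0.071, and Gfap by 1.55. Bdnf (0.23) and Cry1 (−0.16) were closest to 0 without fluoxetine 3, Htr2c (0.0032) and Idi1 (−0.19) without fluoxetine 2, and Srebf2 (−0.11) without vehicle 1. Tap1 (−0.16) and Rims2 (−0.20) were so without vehicle 2, and Acta2 (−0.31), Rgs5 (−0.13) and Irf1 (−0.11) without vehicle 3.

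**Figure D2:**
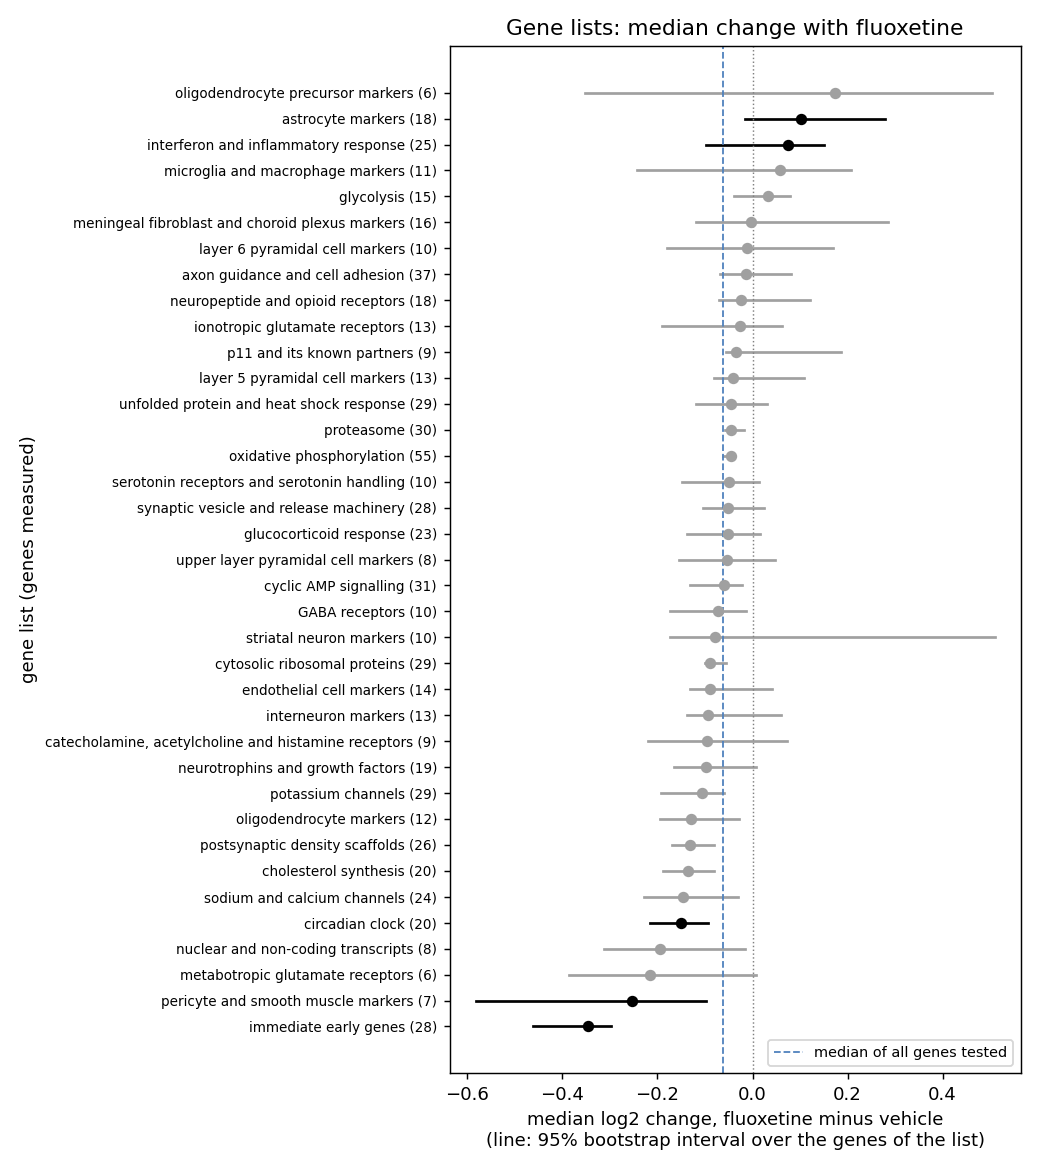
For each of the 37 gene lists, the point is the median log2 change (fluoxetine minus vehicle) of its measured genes and the line its 95% bootstrap interval over genes, in black where limma's camera test at the preset correlation gave an adjusted p under 0.05. Immediate early genes lie lowest at −0.35, and 32 of the 37 medians lie below 0, with the median of all genes tested (dashed) at −0.06. That count depends on the scaling, as quantile normalization and the median shift turned many of these medians above 0.

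All 5 list calls (3 lower, 2 higher) rest on the preset correlation, and each of the 10 ways of splitting the 6 arrays into 3 and 3 called 1 or more lists, up to 9, with the immediate early list called in 3 of the 9 that are not the real one. The arrays did not part by treatment: the split of fluoxetine 1, fluoxetine 2 and vehicle 3 against the rest gave 2799 probe sets at an unadjusted p under 0.05 and 28 past the adjusted threshold, against 563 and 0 for the real groups.

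**Figure D3:**
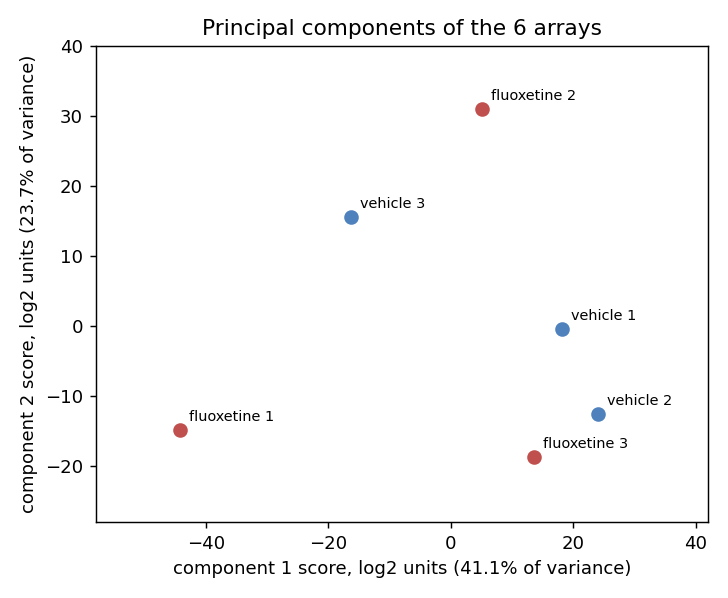
Each point is 1 array placed by its scores on the first 2 principal components of the tested probe sets (log2 intensity), which hold 41.1% and 23.7% of the variance, with fluoxetine in red and vehicle in blue. The 2 groups are interleaved, and fluoxetine 1 lies apart at −44.3 on component 1.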

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

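The tests without fluoxetine 1 (as explanations, the omission itself being planned), without it and vehicle 2, without Gfap, of the synaptic vesicle genes and of exchanged replicate 3 labels were chosen after the results were seen. Probe sets below the filter, outside the comparison, stood out by their direction: their median log2 change was 0.053, 72.6% were higher with fluoxetine, and 2794 were higher against 157 lower at an unadjusted p under 0.05. Their median level was 3.23, 3.26 and 3.28 in log2 on the fluoxetine arrays and 3.20, 3.16 and 3.21 on the vehicle arrays.

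Of the explanations for the lower immediate early genes, fluoxetine 1 as the sole source is argued against by the list median of −0.27 without it. Camera still called the list there, which adds little, since other splits of the arrays called it too. Without both fluoxetine 1 and vehicle 2 the call ended (median −0.22, camera adjusted p = 0.221, with fewer arrays, 2 a side). A trend with intensity is argued against by random lists matched on mean expression, of which none of 10000 went as low (percentile 0.01, the smallest they can give, lowest median −0.17). A smaller share of neuronal RNA as the sole source is argued against by the synaptic vesicle genes (median −0.051, 95% bootstrap interval over genes −0.10 to 0.02). Other neuronal lists fell further: metabotropic glutamate receptors by −0.22 (interval −0.39 to 0.01), sodium and calcium channels by −0.15 and postsynaptic scaffolds by −0.13. These intervals do not cover the spread between arrays, so a smaller contribution of this kind stays open. The 10 splits of the arrays are too few for a share under 0.05: the real absolute mean change was 0.39, reached by 1 split, the real one, and the highest other was 0.34, while camera called the list in 3 of the 9 others too. RNA quality of fluoxetine 1 and vehicle 2 stays open, not tested for this list: nuclear and non-coding transcripts deviated there by −0.33 and 0.36, and vehicle 2 had the largest 3′ minus 5′ difference of control transcripts (2.91 in log2, the others 2.53 to 2.76). An effect of the drug on activity-dependent transcription stays open as a hypothesis, and so do differences in handling or time of day before the tissue was taken, for which the labels give nothing to test. Circadian clock genes, of which 18 of 20 measured were lower, bear on time of day but were not tested for a shift of phase.

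The arrays did not group by treatment. Other splits gave at least as many probe sets at an unadjusted p under 0.05 in 7 of 10 cases with the real one included (563 real, highest other 2799), and at least as many lists called in 7 of 10 (5 real, highest other 9); 10 splits are too few for a share under 0.05. The highest count came from the real grouping with the replicate 3 arrays exchanged, which points to a structure of the samples other than the labelled groups. Both of those arrays correlated better with the other group than with their own, by 0.0071 for fluoxetine 3 and 0.0017 for vehicle 3. These correlations use the same values that singled out the split, so they are no independent sign. Exchanged labels may be a candidate explanation, but the immediate early list then changed by less (0.24 in absolute mean). With no marker of the drug, exchanged labels cannot be told apart from a shared source of variation. On fluoxetine 1, the array furthest out, the 3′ minus 5′ difference of control transcripts was 2.61 in log2, inside the range of 2.53 to 2.91 of the others. This argues against degraded RNA with a stronger 3′ bias there. RNA of other cell types stays open. Oligodendrocyte precursor markers lay 0.43 above the other arrays in the median with 4 of 6 members, and astrocyte markers 0.34 with 14 of 18, just under the bound of 80%. Non-neuronal markers did not all rise there. Meningeal markers deviated by 0.15 (10 of 16 above) and oligodendrocyte markers by 0.06 (6 of 12). Microglia markers deviated by −0.43 (2 of 11), pericyte markers by −0.22 (0 of 7) and endothelial markers by −0.12 (6 of 14).

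The higher astrocyte list was weighed in the same way. Gfap as the sole source is argued against by a median of 0.09 without it, though the mean dropped from 0.33 to 0.15. Camera still called the list without Gfap (adjusted p = 0.0074), but this adds little, as every split of the arrays called lists at the preset correlation. The call depended on fluoxetine 1, since the median without that array was 0.015 and the call was lost. That array was not the only one raised. Fluoxetine 3 had a list mean of 10.63 in log2, above the highest vehicle mean of 10.29, with 12 of 18 markers above the other arrays. More astrocyte RNA in the fluoxetine samples stays open, as 11 of 18 markers were higher, between the 14 and the 9 set as bounds. After either quantile normalization or the median shift it was 16 of 18, past the upper bound. Against more astrocyte RNA, the bright markers Gja1 (14.51 against 14.66 in log2) and Glul (13.90 against 13.92) were not higher with fluoxetine. Glul was chosen after its values were seen. Another marker, Aldoc, was higher by 0.21, but differed by −0.11 without fluoxetine 1. Whether a small added share could show at the levels of Gja1 and Glul was not tested. A change of Gfap within labelled cells, as the labels allow for non-neuronal ones, was not tested.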

How the results depend on the processing

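The alternatives without fluoxetine 1 and vehicle 2 together, without Per1 and without Gfap were chosen after seeing the data, as was the error used to count a sign change. No alternative gave a probe set past the adjusted threshold, including 0.10 in place of 0.05. Of 3875 values compared with their main value, 3781 are counted as unchanged, which for list medians and genes includes a change of sign within the standard error, 41 lost a call or shrank, 26 gained and 27 reversed. In all, 79 list medians changed sign under some alternative: 18 are counted as reversed with the standard error between arrays as tolerance, and 49 would be with the standard error over list members, the error used at first. Likewise 31 named gene values changed sign within their standard error. Immediate early genes were called in all 18 settings at the preset correlation (largest adjusted p = 0.0022). Over all 20 settings the calls numbered 10 for circadian clock genes, 12 for interferon genes, 16 for astrocyte markers and 11 for pericyte markers. Trend and robust variance estimates entered only the test of probe sets, so for lists that setting repeats the main test and adds nothing to these counts. Lists not called in the main setting were called in others of these 18: cholesterol synthesis in 9, meningeal markers in 4, microglia in 3, ribosomal proteins, oligodendrocyte precursors, postsynaptic scaffolds and axon guidance in 2 each, and glycolysis, potassium channels and sodium and calcium channels in 1 each. Causes were not tested, except that fewer arrays or members weaken a test by construction. Low signal over background limits the genes below the filter and those just above it.

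The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at −0.25, −0.03 and −0.50, and 0 arrays correlated best with their own number. With the replicate block there were 350 probe sets at an unadjusted p under 0.05 (103 higher, 247 lower), 0 past the adjusted threshold and 4 lists called, the circadian clock list (−0.15, adjusted p = 0.060) no longer among them.

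Without a filter, 2631 probe sets had an unadjusted p under 0.05 (1728 higher, 903 lower), and calls were lost for interferon genes (0.074, adjusted p = 0.286), astrocyte markers (0.10, 0.149) and pericyte markers (−0.10, 0.286), and gained for cholesterol synthesis (−0.14, 0.0086) and ribosomal proteins (−0.09, 0.026). With a group mean of 50 in at least one condition, the meningeal median was 0.036 and called. A minimum of 100 gave 3 lists, without circadian clock genes (−0.15) and interferon genes (0.0065). Quantile normalization gave 3 lists, without circadian clock genes (−0.086) and interferon genes (0.073), and turned layer 5 (0.029) and layer 6 markers (0.056). The median shift lost interferon genes (0.13) and turned layer 5 markers (0.020) and the glucocorticoid response (0.0090). Array weights called 8 lists, lost pericyte markers (−0.24) and turned axon guidance genes (0.0031, called) and layer 5 markers (0.015). Leaving out probe sets that can match several genes gave 3 lists, without circadian clock genes (−0.16) and pericyte markers (−0.24). Averaging a gene's probe sets lost pericyte markers (−0.16) and turned Rps6 (0.015) and Laptm5 (0.39). A threshold of 0.10 gave 8 lists.

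An estimated correlation and fry each called 0 lists, at unmoved medians for immediate early genes (−0.35), circadian clock genes (−0.15), interferon genes (0.074), astrocyte markers (0.10) and pericyte markers (−0.25); at an unadjusted p under 0.05 each gave 1 list, and the smallest adjusted p were 0.927 and 0.801. Without fluoxetine 1 and vehicle 2 the immediate early median was −0.22, and without Per1 the circadian median was −0.14, both no longer called.

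Leaving out 1 array at a time, probe sets at an unadjusted p under 0.05 ranged from 318 (without vehicle 2) to 1198 (without fluoxetine 2) and lists called from 5 to 8. List medians ranged from −0.20 to −0.10 for circadian clock genes, 0.015 to 0.24 for astrocyte markers, −0.47 to −0.13 for pericyte markers and −0.025 to 0.14 for interferon genes. Uncalled lists ranged from −0.063 to 0.017 for layer 5 markers, −0.10 to 0.078 for meningeal markers, −0.043 to 0.044 for axon guidance genes, −0.059 to 0.12 for neuropeptide receptors, −0.075 to 0.040 for the proteasome, −0.16 to 0.066 for interneuron markers, −0.17 to 0.00035 for endothelial markers and −0.10 to 0.0037 for the glucocorticoid response. Among named genes, Lhx6 ranged from −0.63 to 0.027, Ddc from −0.35 to 0.22, Hk1 from −0.022 to 0.45, Cnp from −0.34 to 0.030, Mbp from −0.31 to 0.032, Cspg4 from −0.65 to 0.014 and Gpr17 from −0.64 to 0.11.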

Other observations

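The tests of gene families were chosen after the data were seen. Among 132 families of genes that share a symbol stem and have at least 10 measured members, limma's camera at the preset correlation called 3, and 0 with an estimated correlation (adjusted p = 0.998 for each of the 3). Sox transcription factors, regulators of cell fate and of glial development, had 12 of 14 members higher with fluoxetine and a median log2 change of 0.20 (adjusted p = 9.17e-06), with Sox9 and Sox6 among them, which are also on the astrocyte and oligodendrocyte precursor lists (0.34 and 0.43 above the other arrays on fluoxetine 1). Their median was 0.25 after quantile normalization, 0.26 after the median shift and 0.10 without fluoxetine 1, where the call held (adjusted p = 0.00052). Collagen genes, of which Col1a1 and Col3a1 are also meningeal markers, had 16 of 26 members higher and a median of 0.11 (adjusted p = 0.0046); after quantile normalization the call was lost (median 0.19, adjusted p = 0.093). All 13 Klf genes, zinc finger factors of which Klf4 and Klf10 were also on the immediate early list, were lower, with a median of −0.27 (adjusted p = 0.037), −0.21 under both scalings. Without fluoxetine 1 the Klf median was −0.16 and the call was lost (adjusted p = 0.35).

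The mice were backcrossed from FVB for few generations, so remaining FVB segments that differ between the groups could change neighbouring genes together. Of 326 genes at an unadjusted p under 0.05, 6 neighbouring pairs changed the same way, against a median of 5 and an upper end of the 95% range of 10 in 10000 permutations of the genes along the chromosomes (p = 0.428), which leaves the hypothesis open. One of the pairs was Fos with Jdp2.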
